A study of Homo sapiens with 10 samples.

How the data were processed

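RNA-seq libraries of cells labelled MCF-7, expressing wild-type (WT) or mutant (3A) HA-tagged MTA1 from a lentivirus under puromycin selection, were compared as 2 against 2 libraries, grouped by their titles. Total RNA was extracted with Trizol and libraries were made with a SMARTer cDNA kit, per the labels' protocols. The 6 chromatin immunoprecipitation libraries in the labels were not analysed here.

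Each deposited table listed RefSeq transcripts with NCBI gene IDs, and held an estimated read count and an FPKM value per transcript, per the file headers. The estimated counts were not whole numbers and were deposited without normalization. The FPKM values were scaled by the authors to transcript length and library size, as the unit's name in the file headers says. The aligner, the counter and the use of strand for RNA are not given in the sources used here. The build hg19 and the tools Bowtie2, MACS2, deepTools and ChIPseeker are listed, per the submitters' processing notes, without a role. The replicate 1 files listed 81740 transcripts and the replicate 2 files 67062, of which 62708 were shared. In the replicate 1 files 14217 transcripts were at 0 in both libraries and in the replicate 2 files 0 were, so the tables of the 2 replicates were not made alike. Counts were summed per gene ID. Of 18112 genes listed in any file, 17818 had a symbol in a RefSeq name table for GRCh38.p14, which was used for names only. Coordinates are not given, since that table is of another build. The test used the 16545 genes listed in all 4 files. The 1409 genes listed only in the replicate 1 files and the 158 listed only in the replicate 2 files held at most 485.2 counts in any library.

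Summed counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, glmQLFit and glmQLFTest, no covariate), which left 13942 genes with a common dispersion of 0.00362. A gene passed with a Benjamini-Hochberg adjusted p under 0.05. The SE of a fold change was its size divided by the square root of the F statistic. Within-pair ratios used CPM with 0.1 added. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 6.21 for WT and 5.68 for 3A. That difference includes any from how the tables were made, so it does not show separate cultures, and each library was counted as a replicate because the labels number them as separate samples. The first principal component held 62.3% of the variance. Totals of 19026320 to 20976312 estimated counts put 3 counts, the limit that a count of 0 allows, at 0.143 to 0.158 CPM.

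Gene lists were fixed before the data were examined, 29 in all, and 28 had the minimum of 5 tested genes. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 28 lists. With an estimated correlation, 0 of the 10 calls held (0 lists in all). That test takes its degrees of freedom from the 4 libraries, so almost no list could pass and its outcome decides little about the calls. With the preset correlation the degrees of freedom come from the number of genes. Those p-values are too small where members of a list vary together more than the preset 0.01. fry, which tests whether a list moves on balance in a single direction, called 1 list, hypoxia, and called 26 for change in either direction. The lists were NuRD complex, O-GlcNAc cycling and hexosamine pathway, reported MTA1 targets, estrogen response, luminal identity, p53 targets, homologous recombination and Fanconi anemia, other DNA repair, S phase, G2 and M phase, drug efflux and metabolism, epithelial, mesenchymal, interferon, NF-kB, integrated stress and unfolded protein response, heat shock, hypoxia, cholesterol, NRF2, immediate early, apoptosis, histones, ribosomal proteins, respiratory chain, mitochondrially encoded, and basal-like, fibroblast and leukocyte markers. Named genes were MTA1, the 12 largest rises and 12 largest falls among genes with a symbol, past the threshold, with a mean of at least 1 CPM and both 3A libraries beyond both WT libraries, and from each list the up to 4 members with the lowest p (for other cell types, the highest level). STC1, DUSP4, DUSP6, CDKN1A, ESR1, GATA3, TFF1, TFF3, PGR, KRT8, KRT18, CDKN2A, CDH1, SERPINB4, HBA1, KRT5, KRT14, KRT6A, KRT6B, TP63, TBX3, XBP1 and the component genes of read-through loci were named after their values were seen.

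On simulated counts for 13906 genes with 100 genes changed 1.5-fold and 100 changed 2-fold, edgeR recovered 76% and 86%, with 3.6% false calls among 168, and made 0 calls when nothing was changed. DESeq2 1.42.0 recovered 60% and 77%. The simulation drew genes independently at the trended dispersion, with no difference between the pairs of files and no changes under 1.5-fold. These rates are therefore not error rates of the calls on the real libraries. Alternatives set before the data were examined were DESeq2 size factors, upper quartile factors, no low-count filter, a minimum mean of 5 CPM, a replicate block, DESeq2, limma on log2(FPKM + 1), leaving out each library, a 2-fold minimum, an adjusted p under 0.1, an estimated correlation and fry. A correction for transcript length, as loess offsets per library, was added after seeing the data. Scripts ran in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.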

Results

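RNA was sequenced from cells labelled MCF-7, an estrogen receptor-positive human breast cancer line of luminal type, after stable lentiviral transduction with HA-tagged MTA1. MTA1 is a subunit of the NuRD chromatin remodelling and histone deacetylase complex. WT cells carried the wild-type protein. 3A cells carried a mutant in which alanine replaced 3 serines, which the labels give as sites of O-GlcNAc, a single-sugar modification of nuclear and cytoplasmic proteins. There were 2 WT and 2 3A RNA libraries, with 19380677 and 19346590 estimated counts for WT replicates 1 and 2, and 20976312 and 19026320 for 3A replicates 1 and 2. No library of untransduced or empty-vector cells was analysed here, so each value compares the mutant line with the wild-type line and has no background level beside it. The 6 chromatin immunoprecipitation libraries of the series (2 input, 2 WT and 2 3A) were not analysed here. Levels are normalised read counts (CPM, relative to library size with TMM scaling), with mean ± SD over n = 2 libraries. Fold changes are log2 values of 3A against WT with their SE, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13942 genes. Nothing in the labels says whether replicates were separate cultures, so edgeR's p-values measure the spread between these libraries, which may be technical.

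The transcript of MTA1 (gene ID 9112), the expressed gene itself, was lower in the mutant line. Its level was 590 ± 61.2 CPM in WT and 262 ± 24.5 CPM in 3A, a log2 fold change of -1.17 (SE 0.0916, adjusted p = 0.00104). The estimated counts were 10452 and 11882 in the WT libraries and 5272 and 5412 in the 3A libraries. These values sum the transgene and the endogenous gene, which the tables do not separate. The files of replicate 1 and replicate 2 listed different sets of transcripts, so the ratio was also taken within each pair of files, where it was -1.16 and -1.18. The isoform NM_004689.3 stood at 434 and 500 CPM in WT replicates 1 and 2 and at 162 and 167 CPM in 3A replicates 1 and 2. The other listed MTA1 isoforms together stood at 113 and 133 CPM in WT and at 82.9 and 113 CPM in 3A. Every comparison below is therefore between lines that differed in the level of MTA1 transcript as well as in its sequence.

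**Figure D1:**
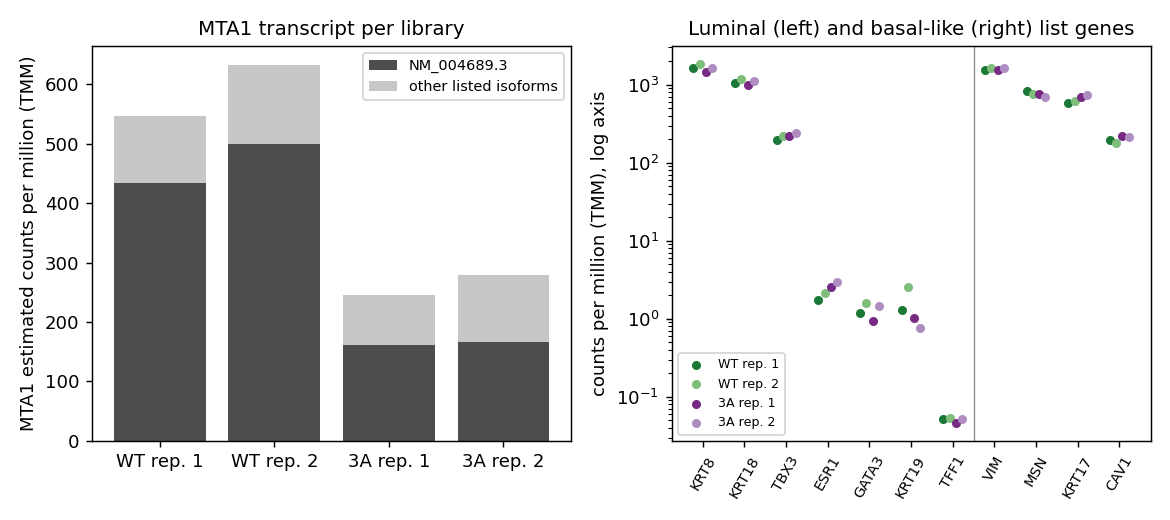
Left, stacked bars of the MTA1 level (CPM) in each library, with isoform NM_004689.3 in dark grey and the other listed isoforms in light grey. Both 3A libraries lie below both WT libraries (245 and 280 against 547 and 633 CPM). Right, CPM on a log axis of luminal (left of the line) and basal-like (right) list genes, a point per library: ESR1, GATA3, KRT19 and TFF1 lie under 3 CPM in every library and VIM lies at 1540 CPM or more.

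The question the design poses is which genes depend on the 3 modified serines of MTA1. It cannot separate these serines from other differences between the transduced lines. The labels do not say that libraries of a group come from separately transduced lines, so p-values may not measure the spread between lines. Of the 13942 genes tested, 2973 (21.3%) passed the threshold, of which 1714 were higher and 1259 lower in 3A. Most of these differences were small, with a median of 1.3-fold, and 90 genes rose and 91 fell by at least 2-fold. All 2973 had both 3A libraries on the same side of both WT libraries, which fixes their direction within each pair of files, and they were selected on these same libraries. Over all tested genes, 64.9% had both 3A libraries on the same side of both WT libraries, against 33.3% by chance for 2 against 2. The share that rose, 57.7% of the genes past the threshold, was 52.9% with DESeq2 size factors, 64.0% with upper quartile factors and 45.5% after a correction for transcript length. It was 77.0% with limma on FPKM values, which changed the unit, the scaling and the test together. The number past the threshold was 1351 without 3A replicate 1, 1765 without WT replicate 2, 1794 with limma on FPKM and 1918 with DESeq2, and it was 4102 without WT replicate 1 and 4583 at an adjusted p under 0.1.

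Among genes with a mean of at least 1 CPM, the largest rises in 3A were between 1.63 and 4.85 on the log2 scale. FBN2, which encodes the extracellular matrix protein fibrillin-2, rose from 22.8 ± 0.146 to 70.5 ± 0.821 CPM (log2 fold change 1.63, SE 0.0708, adjusted p = 0.00013). TNFRSF11B, the secreted decoy receptor osteoprotegerin, rose by 1.77 (SE 0.137) from 2.90 to 9.94 CPM, and the chemerin-binding receptor CCRL2 by 1.67 (SE 0.131) from 4.71 to 14.9 CPM. FAP, a cell surface serine protease, rose by 2.33 (SE 0.299) from 0.582 to 2.95 CPM, and KLF12, a transcriptional repressor, by 2.01 (SE 0.172) from 1.80 to 7.26 CPM. PPFIA2, a liprin scaffold protein of cell contacts and synapses, had the largest value, 4.85 (SE 0.343), from 0.159 to 4.73 CPM. Its WT level rested on 2 and 4 counts, so the size of the rise is uncertain. The log2 value was 4.43 to 5.42 on leaving out 1 library. CRACD (2.53), TBC1D8B (1.90) and PTCHD4 (1.77) also rose. SERPINB3 rose by 1.96 and CARD16 by 2.44. Both can share reads with near-identical paralogs, SERPINB4 (1.01) and CASP1 (0.85, not past the threshold), and ZNF117 (1.89) overlaps another gene. The split of their reads was not measured and is uncertain. The call on ZNF117 ended with limma on FPKM.

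The largest falls began with genes of low or moderate level in WT. KCNH2, the hERG potassium channel, fell from 2.40 ± 0.154 to 0.237 ± 0.190 CPM (log2 fold change -3.27, SE 0.423, adjusted p = 0.00545). It rested on 8 and 2 counts in the 3A libraries, and the log2 value was -4.47 without 3A replicate 1 and -2.67 without 3A replicate 2. SLC2A5, the fructose transporter GLUT5, fell from 4.17 to 0.439 CPM (-3.23, SE 0.257), and the tetraspanin TSPAN18 from 7.26 to 0.940 CPM (-2.95, SE 0.226). NEFH, the heavy neurofilament subunit, fell from 15.3 ± 0.240 to 2.82 ± 0.246 CPM (-2.44, SE 0.128, adjusted p = 0.00037). DPYSL4 (-2.21), the oxysterol-binding protein OSBPL6 (-2.13), the kinase WNK2 (-2.10) and SPINT1 (-1.95), an inhibitor of the hepatocyte growth factor activator, fell as well. The remaining genes of this rule were ABHD14A-ACY1, CORO7-PAM16, CDRT4 and PTGES3L-AARSD1, which overlap neighbouring or component genes, so their counts are uncertain. The first 3 had 0 estimated counts in both 3A libraries, which can come from how the counting shared reads among overlapping transcripts. Against a floor of 3 counts over the group these genes were 98.3-fold, 42.6-fold and 30.5-fold lower, values that are not lower bounds. Their component genes did not pass the threshold (ABHD14A -0.25, ACY1 0.02, CORO7 -0.21, PAM16 -0.18, PTGES3L 0.10, AARSD1 0.14), and TVP23C-CDRT4 rose by 0.76. PTGES3L-AARSD1 had 37.7 and 74.3 counts in WT and 14.4 and 0 in 3A (-3.10, SE 0.714), with a log2 value of -2.17 without 3A replicate 2, which held the 0. CDRT4 rested on 65.7 and 22.8 counts in WT replicates 1 and 2. CORO7-PAM16 rested on 12.2 and 111 counts in the WT libraries, and its call ended with limma on FPKM.

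Genes of the hypoxia response and immediate early genes were lower in 3A. In the hypoxia list, which holds targets of hypoxia-inducible factors, 19 of 30 tested members fell and 1 rose (19 and 2 adjusted over the list alone), with a median log2 fold change of -0.356 (camera adjusted p = 5.08e-09, and 0.455 with an estimated correlation). With so few libraries almost no list could pass with an estimated correlation, here and in the lists below. The camera p-values with the preset correlation take their degrees of freedom from the number of genes. They rest on an assumed correlation of 0.01 and are too small where members vary together more than that. ADM, the vasodilator peptide adrenomedullin, fell from 21.3 ± 1.89 to 6.65 ± 1.26 CPM (-1.69, SE 0.140). ENO2, a glycolytic enolase, fell by 0.86 on the log2 scale, carbonic anhydrase CA9 by 0.85 and the stress-responsive gene NDRG1 by 0.76, from 894 ± 1.45 to 529 ± 5.83 CPM. STC1, the member that went the other way, rose by 0.40. Of 30 immediate early genes, the transcripts induced within minutes of growth factor or stress signals, 18 fell and 2 rose (19 and 3 adjusted over the list alone), with a median of -0.399 (camera adjusted p = 2.65e-06, and 0.455 with an estimated correlation). JUN fell from 404 ± 56.3 to 211 ± 28.3 CPM (-0.94, SE 0.115) and FOS from 681 ± 62.1 to 366 ± 30.1 CPM (-0.90, SE 0.0841). FOSB fell by 0.68 and EGR1 by 0.59. The members that rose were the phosphatases DUSP4 (0.32) and DUSP6 (1.13). The medians within the replicate 1 and replicate 2 files were -0.36 and -0.36 for hypoxia and -0.37 and -0.36 for immediate early genes.

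**Figure D2:**
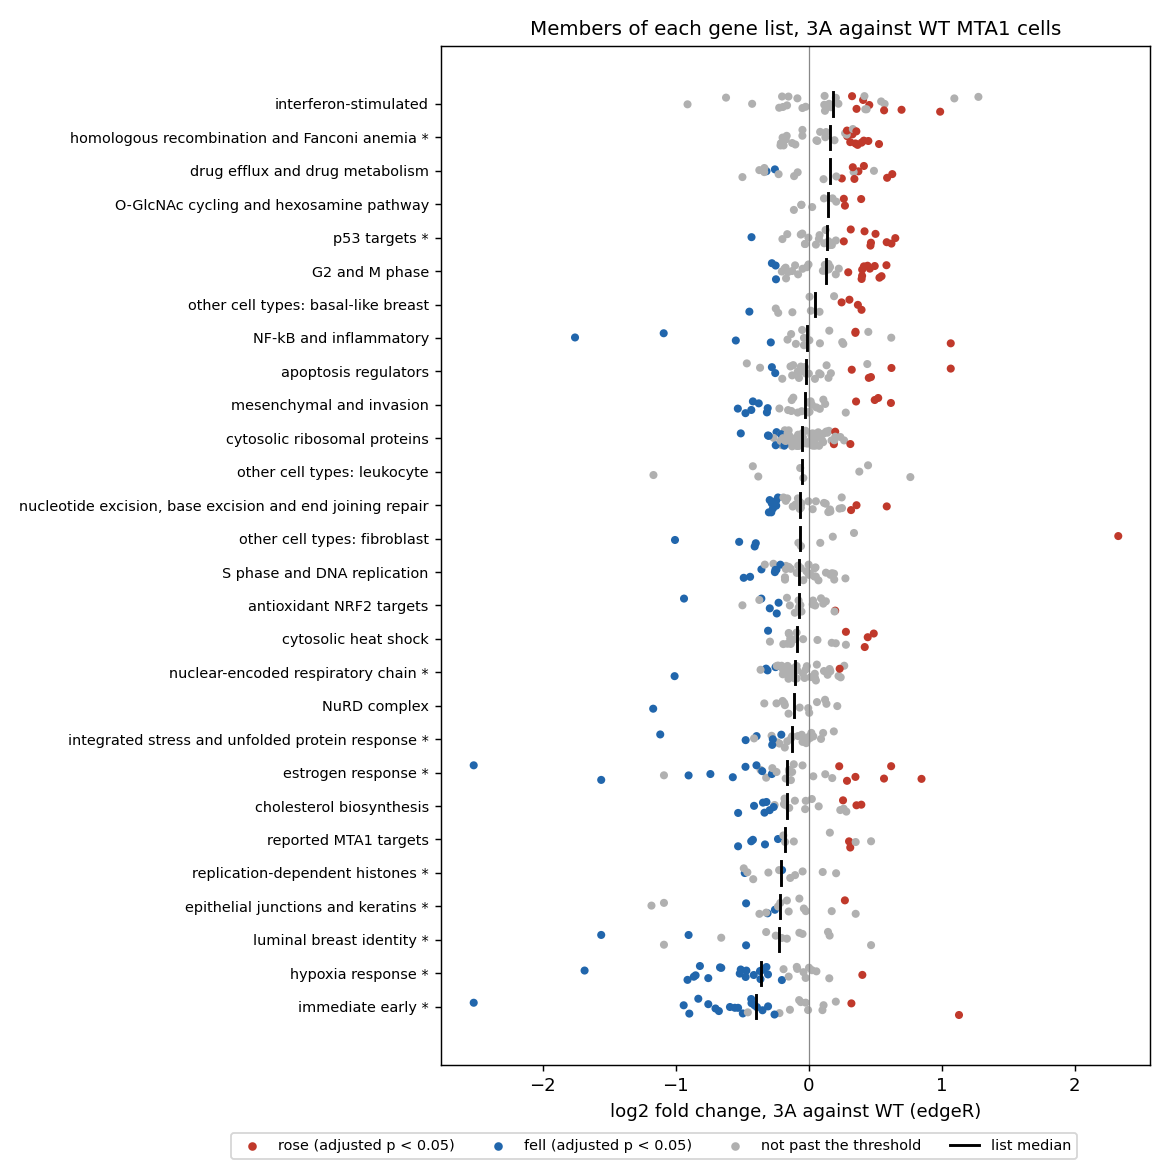
Log2 fold change, 3A against WT, of every tested member of each gene list, a point per gene, coloured by whether edgeR's adjusted p passed 0.05, with the list median as a black bar. An asterisk marks the 10 lists past camera's threshold. The hypoxia and immediate early lists, at the bottom, have medians of -0.356 and -0.399.

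In the list of the integrated stress and unfolded protein response, 6 of 27 members fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.126 (camera adjusted p = 0.0192, and 0.455 with an estimated correlation). Without WT replicate 2 the median was -0.075, still past the threshold. VLDLR, a lipoprotein receptor, fell by 1.12, the mTORC1 inhibitor DDIT4 by 0.47, the phosphatase subunit PPP1R15A by 0.39 and the amino acid transporter subunit SLC3A2 by 0.27 on the log2 scale. DDIT4 is also a member of the hypoxia list, and VLDLR is also known as a target of hypoxia-inducible factors. Of 22 NRF2 targets, which encode antioxidant and pentose phosphate enzymes, 5 fell and 1 rose (5 and 1 adjusted over the list alone), among them HMOX1 (-0.94), G6PD (-0.36), TKT (-0.29) and PGD (-0.24), and the list did not pass (median -0.076, adjusted p = 0.0629), though it did without 3A replicate 1. Among 19 cytosolic heat shock genes, 4 rose and 1 fell (6 and 3 adjusted over the list alone). The chaperone HSP90AA1 rose by 0.42, HSPA4L by 0.44 and the HSP90 cochaperone CHORDC1 by 0.49, whereas the small heat shock protein HSPB1 was at -0.31. That list did not pass (adjusted p = 0.996), with a negative median (-0.091) beside a positive mean (0.031). The calls on SLC3A2, TKT and HSPB1 ended without WT replicate 2 and without 3A replicate 1, and that on PGD on leaving out any 1 library.

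Of 26 p53 targets, 16 did not pass, 9 rose and 1 fell (10 and 1 adjusted over the list alone), with a median of 0.138 (camera adjusted p = 0.0192, and 0.455 with an estimated correlation). RRM2B, a ribonucleotide reductase subunit used in DNA repair, rose from 42.9 ± 0.925 to 64.4 ± 2.84 CPM (0.59, SE 0.0707). The cyclin CCNG1 rose by 0.50 and the death receptor FAS by 0.62, and the antiproliferative gene BTG2 fell by 0.43. CDKN1A, the cyclin-dependent kinase inhibitor p21, was at 387 ± 8.50 and 432 ± 11.3 CPM and did not pass (0.16, adjusted p = 0.084). Of 27 apoptosis regulators, 5 rose and 2 fell (6 and 3 adjusted over the list alone), with an adjusted p of 0.494, a median of -0.022 and a mean of 0.066. The inhibitor of apoptosis BIRC3 rose by 1.07, the pro-apoptotic gene PMAIP1 by 0.47, and the survivin gene BIRC5 fell by 0.28. In the NF-kB and inflammatory list, 3 of 20 members rose and 4 fell (5 and 4 adjusted over the list alone). SOD2 (0.35) rose there while the chemokines CXCL2 (-0.55) and CXCL3 (-1.09) fell, with a median of -0.016, a test direction of up and an adjusted p of 0.72. Of 32 interferon-stimulated genes, 7 rose and 0 fell (7 and 1 adjusted over the list alone), including IFIT1 (0.70), IFI44 (0.99), IFIT2 (0.46) and IFIT3 (0.36), and the list did not pass (median 0.185, adjusted p = 0.0782). The calls on IFI44 and IFIT2 ended without WT replicate 2, that on IFI44 also without 3A replicate 2, that on BIRC5 without 3A replicate 1 and that on IFIT3 on leaving out any 1 library.

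Of 32 genes of homologous recombination and the Fanconi anemia pathway, which repair double-strand breaks and crosslinks, 12 rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 0.162 (camera adjusted p = 0.0479, and 0.542 with an estimated correlation). BARD1 rose from 17.0 ± 1.01 to 22.6 ± 1.29 CPM (0.41, SE 0.0936), the helicase BLM by 0.37, RAD50 by 0.36 and BRCA1 from 58.0 ± 0.189 to 72.0 ± 0.676 CPM (0.31, SE 0.0636). The list call ended without WT replicate 2, where the median was 0.102, without 3A replicate 2, with a minimum mean of 5 CPM and with the length correction, and all 4 of these genes lost their calls without 3A replicate 1. In the list of nucleotide excision, base excision and end joining repair, 3 of 32 genes rose and 8 fell (4 and 8 adjusted over the list alone), with a median of -0.063 (adjusted p = 0.315). The DNA-dependent protein kinase PRKDC was at -0.28, DDB1 at -0.28 and RAD23A at -0.27, and the ligase partner XRCC4 rose by 0.59. Of 34 S phase and replication genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone), including the helicase subunits MCM2 (-0.44), MCM5 (-0.36) and MCM4 (-0.25) and thymidine kinase TK1 (-0.49), with a median of -0.07 (adjusted p = 0.0723). Of 33 G2 and M phase genes, 11 rose and 3 fell (13 and 4 adjusted over the list alone), including the kinetochore genes CENPE (0.58) and CENPF (0.44), the checkpoint kinase TTK (0.55) and HMMR (0.46), with a median of 0.126 (adjusted p = 0.064). The S phase list passed without WT replicate 2 (median -0.111) and without 3A replicate 1, and the G2 and M list without each library in turn except WT replicate 2 (medians up to 0.166). The median of the other repair list was 0.004 without WT replicate 2. The calls on DDB1, RAD23A and MCM5 ended without WT replicate 2 and without 3A replicate 1, XRCC4 without WT replicate 2, PRKDC without 3A replicate 2 and MCM4 on leaving out any 1 library.

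**Figure D3:**
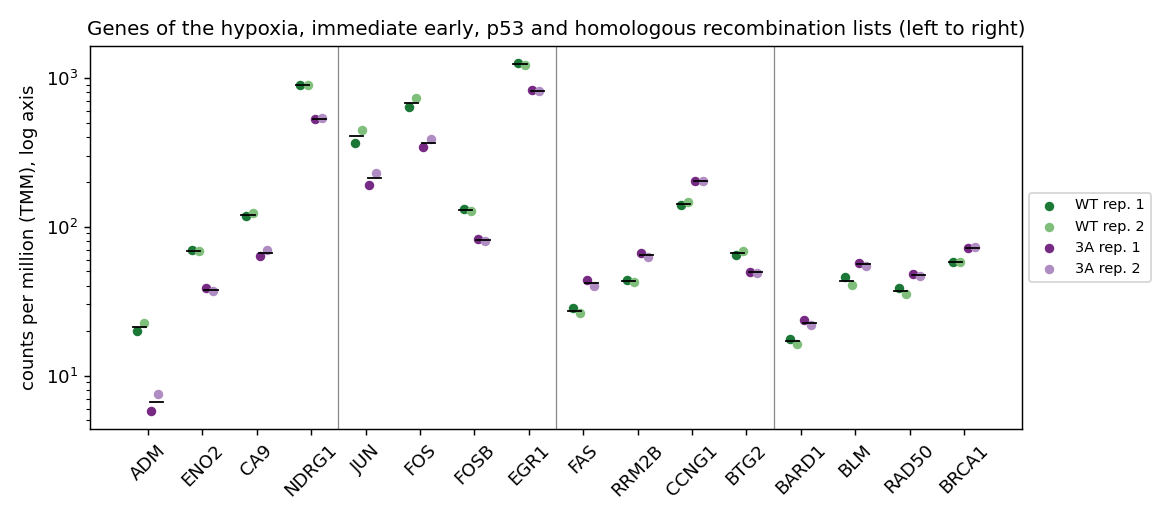
CPM on a log axis of 16 genes, a point per library with a bar at each group's mean: ADM, ENO2, CA9 and NDRG1 of the hypoxia list, JUN, FOS, FOSB and EGR1 of the immediate early list, FAS, RRM2B, CCNG1 and BTG2 of the p53 list, and BARD1, BLM, RAD50 and BRCA1 of the homologous recombination list. In every gene shown, both 3A libraries lie beyond both WT libraries. That comes with the choice of genes past the threshold, since it held for all 2973 of them, and for 64.9% of all tested genes.

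Several luminal markers had low levels in all 4 libraries, and a minority of the tested members of the luminal, epithelial and estrogen response lists fell in 3A. The mean over the 4 libraries was 2.37 ± 0.519 CPM (SD, n = 4) for the estrogen receptor gene ESR1, 1.29 ± 0.293 CPM for the luminal transcription factor GATA3 and 1.42 ± 0.789 CPM for the luminal keratin KRT19. The estrogen-induced genes TFF1 and PGR lay under the limit of 0.143 to 0.158 CPM that a count of 0 allows at these depths, counting error alone, and TFF3 was not listed. The keratins KRT8 and KRT18 stood at 1640 ± 162 and 1090 ± 89.4 CPM (SD, n = 4). With the unlisted TFF3 counted at 0, 11 of the 18 genes of the luminal list were under 10 CPM in every library. Of its 14 tested members, 3 fell and 0 rose (3 and 0 adjusted over the list alone), with a median of -0.226 (camera adjusted p = 0.0418, and 0.521 with an estimated correlation). These were AGR2, a protein disulfide isomerase, which fell from 8.40 to 2.85 CPM (-1.56, SE 0.162), carbonic anhydrase CA12, from 65.9 ± 1.14 to 35.2 ± 1.31 CPM (-0.90, SE 0.0702), and the epithelial transcription factor ELF3 (-0.47). KRT19 did not pass (-1.09, adjusted p = 0.08). In the estrogen response list, 9 of 30 members fell and 6 rose (11 and 6 adjusted over the list alone), with a median of -0.161 (camera adjusted p = 0.0418, and 0.455 with an estimated correlation). AGR2, CA12 and the ubiquitin ligase SIAH2 (-0.57) fell, and the growth factor AREG rose by 0.85. Of 17 genes of epithelial junctions and keratins, 3 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.214 (camera adjusted p = 0.0418, and 0.455 with an estimated correlation). ELF3, desmoplakin DSP (-0.25) and claudin CLDN4 (-0.31) fell and TJP1 rose by 0.27. The call on the luminal list ended without the low-count filter, with a minimum mean of 5 CPM, with limma on FPKM and with the length correction, and its median was -0.116 without WT replicate 2. That on the estrogen list ended under the first 2 of these, and that on the epithelial list under both filters, without WT replicate 2, where the median was -0.119, and with the length correction. Among the genes, CLDN4 and TJP1 lost their calls without WT replicate 2 and without 3A replicate 1, and DSP on leaving out any library but WT replicate 2.

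Markers of other cell types were examined in the same libraries. Of 16 basal-like breast genes, 10 were above 10 CPM in every library. The mesenchymal filament gene VIM stood at 1582 ± 62.5 and 1588 ± 58.1 CPM in WT and 3A, MSN at 794 ± 43.7 and 729 ± 49.2 CPM, KRT17 at 603 ± 32.9 and 716 ± 41.3 CPM and CAV1 at 189 ± 10.9 and 216 ± 4.14 CPM. The basal keratins KRT5, KRT14, KRT6A and KRT6B were at most 0.465, 0.422, 0.0578 and 0.058 CPM in any library, and TP63 at most 2.62 CPM. In that list 4 of 12 tested genes rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.048 (adjusted p = 0.334). KRT17 was among those that rose (0.25, adjusted p = 0.0381), a call that ended on leaving out any library but WT replicate 2. In the fibroblast list, 1 of 10 rose and 4 fell (2 and 4 adjusted over the list alone), with a median of -0.068 beside a mean of 0.046 (adjusted p = 0.334) and medians from -0.208 without 3A replicate 2 to 0.013 without WT replicate 2. The collagen gene COL5A1 fell from 898 to 677 CPM (-0.41), FAP rose, and COL1A1 (0.18), THY1 (-0.06) and ACTA2 (0.09) did not pass. In the leukocyte list, 0 of 8 genes passed with edgeR (0 adjusted over the list alone), with a median of -0.053 (adjusted p = 0.624) that ranged from -0.371 without WT replicate 2 to 0.168 without WT replicate 1. Unadjusted edgeR p-values under 0.05 were those of CSF1R (0.0121) and HBA1 (0.0242), and CSF1R passed with DESeq2 size factors, without 3A replicate 2 and with the length correction. The levels of CD68, CSF1R, CD19 and LYZ in WT were 27.0, 10.0, 2.16 and 1.5 CPM. Of 28 mesenchymal and invasion genes, 4 rose and 7 fell (4 and 7 adjusted over the list alone), with a median of -0.029 (adjusted p = 0.315). Leaving out 1 library put that median at -0.101 to -0.029. Fibronectin FN1 rose by 0.62 and tenascin TNC by 0.52, and TGFBI (-0.53) and the plasminogen activator inhibitor SERPINE1 (-0.48) fell.

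Among 14 genes of the NuRD complex, MTA1 fell and 0 rose (6 fell and 1 rose adjusted over the list alone), with a median of -0.11 (adjusted p = 0.11), and the list passed without WT replicate 2 and without 3A replicate 1. The list includes MTA1, whose summed level takes in the transgene, and the list was not tested without MTA1. The deacetylases HDAC1 (-0.20) and HDAC2 (0.21) and the remodeller CHD4 (-0.18) did not pass. Of 10 genes of O-GlcNAc cycling and the hexosamine pathway, 3 rose and 0 fell (3 and 0 adjusted over the list alone), with a median of 0.147 (adjusted p = 0.0782). That median was 0.074 to 0.243 on leaving out 1 library. PGM3, of the pathway that makes the sugar donor, rose by 0.39. OGT, which adds O-GlcNAc, rose from 307 ± 5.37 to 370.4 ± 7.49 CPM (0.27, SE 0.0568), and GFPT1, the first enzyme of the pathway, by 0.26. The calls on OGT and GFPT1 ended with the length correction, without WT replicate 2 and without 3A replicate 1, and OGA, which removes the sugar, was at 0.21 (adjusted p = 0.0847). Of 13 genes reported as MTA1 targets, 2 rose and 5 fell (3 and 7 adjusted over the list alone), with a median of -0.178 (adjusted p = 0.187). The nuclear receptor NR4A1 fell by 0.53 and MYC by 0.43, from 699 ± 30.6 to 518 ± 29.9 CPM, and the phosphatase PTEN rose by 0.30, a call that ended without 3A replicate 1 and with the length correction.

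In the remaining lists the differences were small or mixed. Of 41 nuclear-encoded respiratory chain genes, 4 fell and 1 rose (4 and 0 adjusted over the list alone), with a median of -0.103 (camera adjusted p = 0.0479, and 0.455 with an estimated correlation). NDUFB8 fell from 94.0 ± 12.1 to 46.8 ± 5.81 CPM (-1.01, SE 0.113), and NDUFV1 (-0.32), CYC1 (-0.31) and SDHA (-0.25) fell less. Of 12 replication-dependent histone genes, 2 fell and 0 rose (1 and 0 adjusted over the list alone), with a median of -0.212 (camera adjusted p = 0.0479, and 0.515 with an estimated correlation). These were H2BC21 (-0.48) and H2BC12 (-0.20), whose reads can be shared with near-identical histone genes, and H2AC19 (-0.42) and H3C4 (-0.46) did not pass. The calls on these 2 lists were kept in 4 and 3 of 13 alternatives. Of 77 cytosolic ribosomal protein genes, which can share reads with pseudogenes, 3 rose and 7 fell (1 and 2 adjusted over the list alone). Among them were RPLP2 (-0.51), RPL10 (-0.31), RPL8 (-0.24) and RPL34 (0.31), and the list median was -0.049 (adjusted p = 0.157). Of 24 cholesterol biosynthesis genes, 3 rose and 7 fell (4 and 8 adjusted over the list alone), with a median of -0.162 (adjusted p = 0.077). The regulators SREBF2 (-0.41) and INSIG1 (-0.34) and the reductase DHCR24 (-0.26) fell and SC5D rose by 0.40. Of 20 genes of drug efflux and drug metabolism, 7 rose and 2 fell (7 and 4 adjusted over the list alone), with a median of 0.159 (adjusted p = 0.334). On leaving out 1 library that median was 0.064 to 0.175. The oxidase CYP1B1 rose from 101 ± 1.04 to 156 ± 1.18 CPM (0.63, SE 0.0591), the topoisomerases TOP2A by 0.41 and TOP1 by 0.33 and the transporter ABCC3 by 0.37. Calls ended without 3A replicate 1 for INSIG1, RPL34 and TOP1, there and without WT replicate 2 for NDUFV1, CYC1, RPL10 and SC5D, without either of these or 3A replicate 2 for SDHA, RPL8 and DHCR24, and on leaving out any 1 library for H2BC12. The mitochondrially encoded list had 0 members in the files.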

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

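With groups of 2 libraries and a single contrast, neither a sample far from its group nor a difference between contrasts was looked for. The search was for signal outside the genes tested, against the limit of 3 counts that a count of 0 allows, since there were no control samples; these genes were named after their values were seen. Of the genes listed in only 1 pair of files, 5 had more than 3 estimated counts in both libraries of that pair. CCDC169-SOHLH2, a read-through locus that overlaps its component genes, had 30.8 counts in WT replicate 1 and 47.1 in 3A replicate 1. RIMBP3C had 10.8 and 17.3 counts in WT and 3A replicate 2, and the collagen gene COL1A2 had 14 and 9 there. LOC101929599 had 5.6 and 4.3 counts and PCDHGB3, of a protocadherin cluster with shared exons, 3.3 and 5.6 in WT and 3A replicate 1. None of the 5 has a value in the other pair of files, so no comparison between the lines was made from them.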

How the results depend on the processing

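The length correction was chosen after seeing the data, and the other alternatives before. MTA1 was lower in 3A and past the threshold in all 12 alternatives, with log2 fold changes of -1.28 to -1.06. The count of 2973 genes (1714 rose, 1259 fell) became 1918 with DESeq2 (942 rose), 1794 with limma on FPKM (412 fell; 77.0% rose), 181 with a 2-fold minimum (90 rose, 91 fell) and 4583 at an adjusted p under 0.1 (2118 fell). Leaving out 1 library gave 1351 to 4102 genes (804 to 1980 rose, 547 to 2122 fell), with the lone library assumed to vary like the other group; the count moved by over 1.5 times without 3A replicate 1 (1351) and without WT replicate 2 (1765). The length correction kept 2419 of the 2973 genes among 2907 (1322 rose, 1585 fell). The labels do not say that a replicate number marks a shared culture or batch, but the tables of the 2 numbers were not made alike, replicate 2 minus replicate 1 had a similar trend with transcript length in WT and 3A (Spearman -0.142 and -0.149 across genes), and deviations of same-numbered libraries correlated across genes at 0.183. With a replicate block 7498 genes passed (3569 rose, 3929 fell), including all 2973. Of the 10 lists past camera's threshold, 5 passed with the length correction, 4 with a minimum mean of 5 CPM, 1 with fry in a single direction and 0 with an estimated correlation; of all 28 lists, 26 passed with fry in either direction, 18 with the replicate block, 26 with fry in either direction with the block and 0 with block and estimated correlation. Leaving out 1 library gave 8 to 13 lists. The calls on hypoxia, immediate early, p53 and integrated stress lists were kept in 11 of 13 alternatives with camera. The losses were those with an estimated correlation, with and without the block, where almost no list could pass with so few libraries. With fry in a single direction hypoxia passed (adjusted p = 0.0234), and immediate early (0.0703), p53 (0.0653) and integrated stress (0.0703) did not. With the block, fry in a single direction called 8 lists, with hypoxia at 0.0479, immediate early at 0.0419, integrated stress at 0.0479 and p53 at 0.0568. The 9 lists called with the block and not without it were NuRD (adjusted p = 0.000423), reported MTA1 targets (0.00423), ribosomal proteins (0.000423), G2 and M phase (0.0116), S phase (0.0168), O-GlcNAc (0.0168), NRF2 (0.0168), cholesterol (0.0472) and drug efflux (0.0472), at 0.519 to 0.532 with block and estimated correlation, and histones lost their call (0.235). With the length correction the homologous recombination median went from 0.162 to 0.152, the epithelial from -0.214 to -0.245 and the luminal from -0.226 to -0.252, with adjusted p just over the threshold, whereas the respiratory chain median went from -0.103 to -0.056 and the histone median from -0.212 to -0.163. Of 1505 values of 129 named genes, 1357 kept direction and side of the threshold, 124 lost the call, 24 gained it and 0 reversed; of 363 list values the numbers were 296, 49, 18 and 0. The cause of these changes was not tested, except that a 2-fold minimum and a looser threshold change the count by construction. The NuRD list holds MTA1 itself, so its call with the block takes in the transgene. Pseudocount and filter choices planned for tables without counts did not apply. Depth limits values under about 0.158 CPM, and 2 libraries per group limit the estimate of the spread.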

Other observations

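Families of genes that share a symbol stem were looked at after the data were seen, 92 families of at least 15 tested genes, leaving out uninformative stems. The CEP family, which encodes centrosome and cilium proteins, passed with camera's preset correlation: 18 of its 37 genes rose and 1 fell, with a median log2 fold change of 0.33 (adjusted p = 0.000927, and 0.955 with an estimated correlation). After the length correction 14 rose and 2 fell, with a median of 0.23 (adjusted p = 0.00834). Families that did not pass included the ZNF zinc finger genes, of which 60 of 430 rose and 21 fell (median 0.16, adjusted p = 0.169), the GOLGA golgins, 5 and 1 of 23 (0.34, 0.182), and the TSPAN tetraspanins, of which 0 of 17 rose and 5 fell (-0.20, 0.133).

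All tests of explanations in this part were chosen after the results they bear on had been seen. The first pattern is the lower level of the hypoxia and immediate early lists in 3A. Longer transcripts tended to be higher in 3A (Spearman 0.201 across genes, which are not independent replicates), but after the length correction, which took that to 0.009, the list medians were -0.35 (95% bootstrap interval over genes -0.47 to -0.20) and -0.37 (-0.51 to -0.21), which argues against the length trend as the whole cause. Each pair of files holds a WT and a 3A library, so a difference between the pairs cannot by itself give the difference between the groups. Replicates of a line did, however, differ along the length trend (Spearman of replicate 2 minus replicate 1 with length -0.142 in WT and -0.149 in 3A). On the first principal component, WT replicates 1 and 2 lay at -15.85 and -26.41, and 3A replicates 1 and 2 at 25.04 and 17.21. A technical difference of that kind between the groups was therefore not excluded. The mutated serines and the lower MTA1 transcript of the 3A line (-1.17) cannot be told apart, since they differ together in every library. Transcript length was the only technical trend corrected for, and base composition and RNA integrity were not examined. A different density or handling of the cultures also stays open and was not tested.

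The second pattern is the low level of luminal markers in libraries labelled MCF-7. For luminal cells with a minority of other cells mixed in, the highest value of ESR1, PGR, GATA3, KRT19 and TFF1 in any library was 2.96 CPM. TFF3 was not listed, so it has no value here. These genes define the pattern and were picked after their values were seen, so the test restates the pattern and decides nothing further. The keratins KRT8 and KRT18 of the same list averaged 1640 and 1090 CPM. MCF-7 cells that lost their luminal genes in culture are argued against by CDKN2A, a gene widely described as deleted in MCF-7, which stood at 376 CPM or more in every library; that deletion is background knowledge, not a value of these tables, and whether it held in the stock used was not tested. Cells that are not luminal for another reason remain a candidate explanation, a wrong label among them. On a wrong label CDKN2A bears only through that background knowledge, and no other value here was tested against it. The epithelial cadherin gene CDH1 stood at 2.01 to 3.0 CPM over the libraries and VIM at 1540 CPM or more, and neither was weighed against the label. Of 16 basal-like list genes, 10 were above 10 CPM in every library. The medians were 5.55 CPM for the luminal list, with TFF3 counted at 0, and 62.1 CPM for the basal-like list. These values do not make the cells basal, since KRT5, KRT14 and KRT6A were under 0.5 CPM and TP63 under 3 CPM in every library, while TBX3 (220 CPM) and XBP1 (124 CPM) of the luminal list were high.

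The third pattern is the lower MTA1 level in 3A. A change of the endogenous gene that lowered its isoforms alike is argued against, as far as the split of reads among isoforms holds. The isoforms other than NM_004689.3 had log2 ratios of -0.44 and -0.24 in the 2 pairs of files, against -1.42 and -1.59 for NM_004689.3. The fall of that isoform exceeded that of the others by 0.98 or more (differences of -0.98 and -1.35), in line with different expression of the transgene in the lines, if the transgene is read as that isoform. The values of the other isoforms are pooled, and single ones moved differently in the 2 pairs. XM_017021759.1 had 412 and 255 counts in WT and 3A replicate 1, and 861 and 825 in WT and 3A replicate 2. NM_001203258.1 had 597 and 493 counts in WT and 3A replicate 1, and 388 and 453 in WT and 3A replicate 2. The pooled values do not argue against an endogenous change that differed between isoforms. How the authors' counting shared reads among isoforms is not known, and whether the protein levels differ was not measured here.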
